A study of Homo sapiens with 18 samples.

How the data were processed

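Per the labels, RNA was taken from HaCaT and TIGK cells with Trizol, purified with a clean-up kit, and 1 µg of total RNA went into each library, which a sequencing company prepared. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used with the human genome build hg38; the notes do not state what each tool did, which annotation release was used, or whether the libraries kept strand information. Per the column headings of the deposited files, the authors supplied read counts and FPKM for 58735 annotated genes in 18 libraries, gene annotation with chromosome, start and end, and 10 tables of comparisons. The deposited count table holds whole numbers of reads per gene. Each FPKM value of the authors equals the count divided by gene length and by one constant per column; these constants are proportional to median-of-ratios size factors, with a largest relative deviation of 3.3e-08. The authors' deposited comparison tables give log2 fold changes, a score per gene (the test statistic) and p-values with adjusted p-values; the tool is not named, and the column headings are those of DESeq2 results.

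The columns of the files carry a letter, A, B or C, within each line and time. The labels number the replicates and do not tie the numbers to the letters, so libraries are named here by line, time and letter. Nothing in the labels says that the 3 replicates of a group were separate cultures. If they were not, the p-values measure only the spread between these libraries, which may be technical. The series holds no unscratched culture kept for 24 h, so time since the scratch and time in culture run together.

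Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, which left 17409 genes; libraries were scaled with TMM; and a quasi-likelihood model with 6 group means was fitted to all 18 libraries, with 12 residual degrees of freedom. Levels are given as CPM, the usual scaling of a read count by library size, here the TMM-scaled size, and as the mean ± SD of the 3 libraries of a group (SD, n = 3). Fold changes are the model's fitted ratios with a prior count of 0.125. The SE beside a log2 fold change is its absolute value divided by the square root of the test's F statistic, an approximation. A gene was called at a false discovery rate under 0.05 (Benjamini-Hochberg, over all genes tested in the comparison), and every adjusted p of a gene is this two-sided edgeR value unless another tool is named. Where a group had no count in any of its libraries, the fold is a lower bound computed with 3 counts in each library of that group, written as at least N-fold. Where a group held 1 to 3 counts in total, levels and counts are given and no fold. These bounds cover counting error only.

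The design, the lists and the rule for naming genes were fixed before the data were examined. The rule took protein-coding genes whose symbol occurs once in the table (1745 rows share their symbol with another row) and that were called. The 3 libraries of one group also had to lie above the 3 of the other. Chance separates 3 from 3 in this way for 10% of genes. It took the 10 largest fold changes each way between lines at 0 h with at least 20 CPM in the higher group, the next 5 each way at 6 h and at 24 h, the 8 largest each way for each response within a line with at least 10 CPM, and the 6 largest each way for the line difference in response with at least 10 CPM in 1 of the 4 groups and no demand on separation. From each list described, up to 4 members with the lowest adjusted p were taken, or those with the highest CPM where none passed. TERT and CDKN2A were always named. Genes with near-identical copies elsewhere in the genome may hold reads of their copies, and this is stated where such a gene is named. List members were matched by gene symbol.

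The 29 lists covered basal keratinocyte genes, epidermal differentiation and cornified envelope, oral mucosa identity, HOX genes, wound-activated keratins and alarmins, simple-epithelial keratins, mesenchymal transition, matrix proteases and inhibitors, integrins and wound matrix, immediate-early and AP-1 genes, growth factors, inflammatory cytokines and chemokines, interferon-stimulated genes, antimicrobial and secreted defence genes, S phase, G2/M, p53 targets, genes of immortalised cells, cholesterol synthesis, hypoxia and glycolysis, NRF2 and aryl hydrocarbon receptor targets, YAP targets, TGF-beta targets, the unfolded protein and integrated stress responses, markers of fibroblasts, melanocytes, immune cells and endothelium, and mitochondrially encoded transcripts. Each list was tested against all other genes with camera from limma 3.58.1, on log2 CPM with a preset correlation between genes of 0.01, and its p was adjusted by Benjamini-Hochberg over the 29 lists of a comparison. Members are counted as higher, lower, risen or fallen by the edgeR calls over all genes tested; the count adjusted over the list alone is given beside it where it differs. The same test with a correlation estimated from the data for each list is given beside each list call.

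The fit was tried on simulated counts in which known changes had been planted in 200 genes, 50 at each fold. At folds of 1.25, 1.5, 2 and 4 it recovered 6%, 30%, 58% and 84% of them between the lines at 0 h, 16%, 40%, 64% and 76% in HaCaT at 6 h, 12%, 52%, 64% and 74% in TIGK at 24 h, and 0%, 26%, 62% and 64% for the line difference at 6 h. Of the genes called there, 9.18% (9 of 98), 3.92% (4 of 102), 6.48% (7 of 108) and 6.17% (5 of 81) had not been changed. Each unchanged gene had one mean in all groups, taken over the 18 libraries. More genes were called in the real comparisons of the lines at 0 h and of TIGK at 24 h than were changed here. The shares therefore describe the simulated counts only. In such simulated counts, drawn independently for each gene, a shift of 0.5 log2 planted in the interferon list was called by camera. Of the other 28 lists 0 were called.

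No 2 libraries were copies of each other, and 0 pairs were identical. Between replicates, over genes with at least 20 counts in the pair, chi-square per degree of freedom lay between 3.39 and 17.8. Pairs with a letter C library of TIGK gave 13.4 to 17.8, at 0 h, 6 h and 24 h alike. All other pairs gave at most 7.03. Residuals of libraries sharing a letter were compared across times within each line. In TIGK, the 0 h and 6 h libraries of each letter resembled each other across genes (r = 0.20, 0.18 and 0.53, with 0.13 the highest for 2 different letters), and in HaCaT they did not (r = -0.02, -0.08 and -0.02). Residuals within a group are not independent, so a letter C that stands apart at both times also raises r among A and B. The resemblance rests mainly on letter C, and the labels name no pairing. Between 24 h and earlier times r lay between -0.06 and 0.07 in both lines. A replicate block by letter was run as an alternative, common to both lines and within each line, and its value is printed where it matters. Other alternatives were DESeq2 1.42.0, other filters and scalings, limma-trend on log2(FPKM + 1), the libraries of one comparison alone, leaving out each library, fry in place of camera, and leaving out TIGK letter C. Of the genes that the naming rules pick, 5 are not reported here. XIST and Y-linked genes were left out of the text, and no transcript isoforms were studied, since the files hold gene totals only.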

Results

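The series measured RNA by sequencing in 2 lines of human keratinocytes after a scratch wound: HaCaT, an immortal line from skin, and TIGK, a line from gingiva (the gum) immortalised with telomerase. Each line was collected unscratched (0 h) and at 6 h and 24 h after the scratch, with 3 libraries in each of the 6 groups. The question was which differences in gene expression accompany the better healing of oral keratinocytes. The lines were compared at each time, with HaCaT given relative to TIGK, and each line was compared with its own 0 h. Libraries held 14238090 to 25011331 counted reads. In HaCaT they held 15781895 to 16323357 at 0 h, 16132589 to 16811317 at 6 h and 14238090 to 15232613 at 24 h, and in TIGK 16199912 to 25011331, 15690679 to 18039684 and 14763305 to 15367733. The letter C libraries of TIGK at 0 h and 6 h listed 26246 and 25161 genes with at least 1 count, and the other 16 listed 21164 to 22799. The same 2 libraries had the lowest shares of mitochondrially encoded reads, 5.08% and 4.98%, where the other 16 had 5.84% to 8.08%.

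Before the scratch the lines differed in single genes of many kinds, while 0 of the 9 lists called between them keep the call with an estimated correlation. KRT7, a keratin of simple epithelia (chr 12, 52232520 to 52252186, hg38), stood at 710.5 ± 51.5 CPM in HaCaT and 0.727 ± 0.236 in TIGK (SD, n = 3), 1023-fold higher (adjusted p = 3.2e-22). UCHL1, a ubiquitin hydrolase (chr 4, 41256413 to 41268455), had no count in HaCaT and 163 ± 14.4 CPM in TIGK, at least 868-fold lower. The mucosal keratins KRT4 and KRT3 were 111-fold and 332-fold higher in HaCaT, at 84.8 ± 11.1 against 0.701 ± 0.35 CPM and 30.1 ± 10.9 against 0.0763 CPM. CASP14, a protease of cornification, was 291-fold higher, at 104 ± 7.07 against 0.341 ± 0.199 CPM. Among the other largest differences toward HaCaT, MXRA5, ONECUT3 and TFCP2 were 759-fold, 541-fold and 487-fold higher, and OLFM1 and GALNT5, without a count in TIGK, were at least 162-fold and 147-fold higher. NLRP2 (chr 19, 54953130 to 55001142) stood at 189.8 ± 9.94 CPM in HaCaT and at 0.0252 CPM, 2 counts in all, in TIGK. Toward TIGK, the laminin chain LAMC3 (chr 9, 131009082 to 131094473) stood at 146 ± 13.5 CPM with no count in HaCaT, at least 777-fold lower. MGST1, TNFRSF8, TUSC1, HS6ST2, NKX2-5, RNF212 and DMRTA2 had no count in HaCaT either and stood at 47.1 to 116 CPM in TIGK, at least 250-fold to 615-fold lower. TERT, the catalytic subunit of telomerase (chr 5, 1253147 to 1295069), stood at 5.68 ± 0.798 CPM in HaCaT and 38.1 ± 5.51 in TIGK, 6.7-fold lower (adjusted p = 1.9e-13). TIGK was immortalised with telomerase, and gene totals cannot tell TERT reads of an introduced copy from those of the chromosomal gene, at any time. CDKN2A, which encodes p16 and ARF (chr 9, 21967753 to 21995301), was 7.09-fold lower, at 46 ± 4.26 against 326 ± 21.7 CPM.

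Of 40 interferon-stimulated genes, 36 were lower in HaCaT and 1 higher at 0 h, among them BST2, at 0.316 ± 0.194 against 313 ± 39.9 CPM, and MX1, at 3.71 ± 0.387 against 267.5 ± 60.4 (list adjusted p = 1.6e-11 by camera, adjusted p = 0.25 with an estimated correlation). Of 17 mesenchymal transition genes, 13 were lower and 1 higher (adjusted p = 0.00051, adjusted p = 0.064 with an estimated correlation): SPARC stood at 82.5 ± 6.2 against 674.5 ± 26.7 CPM and fibronectin (FN1) at 234.5 ± 6.17 against 662 ± 43.6. Of 6 fibroblast markers 5 were lower (adjusted p = 0.007, adjusted p = 0.14 with an estimated correlation). Decorin (DCN) stood at 0.461 ± 0.183 against 100.4 ± 19.8 CPM. The mesenchymal and fibroblast lists share COL1A1 and LUM among their members. Of 38 epidermal differentiation genes 23 were higher and 4 lower (adjusted p = 0.00047, adjusted p = 0.39 with an estimated correlation): filaggrin (FLG) stood at 37.1 ± 1.77 against 1.39 ± 0.676 CPM and KRT1 at 923 ± 278 against 35.3 ± 5.96, both 26.2-fold higher. Of 30 HOX genes, which encode positional identity along the body, 20 were higher and 5 lower, led by HOXA9, at 73.5 ± 4.22 against 1.36 ± 0.327 CPM (adjusted p = 0.00047, adjusted p = 0.078 with an estimated correlation). Basal keratinocyte genes were higher for 9 of 16 and lower for 3 (lower for 4 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.39 with an estimated correlation). The laminin chains LAMB3 and LAMA3 were 4.61-fold and 3.47-fold higher. That call is lost in the replicate block by letter within line, at 0.053. G2/M genes were higher for 29 of 33 and lower for 0 (adjusted p = 4.9e-08, adjusted p = 0.39 with an estimated correlation), with PLK1 at 171 ± 11.5 against 76.1 ± 5.73 CPM. S phase genes were lower for 21 of 31 and higher for 7 (adjusted p = 0.0079, adjusted p = 0.39 with an estimated correlation), with the helicase subunit MCM4 at 262 ± 7.55 against 813 ± 22.2 CPM. Hypoxia and glycolysis genes were lower for 19 of 26 and higher for 2 (adjusted p = 0.00069, adjusted p = 0.39 with an estimated correlation), with BNIP3 at 51.5 ± 2.85 against 208 ± 12.6 CPM.

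The other 20 lists were not called at 0 h, with adjusted p from 0.11 to 0.97. Oral mucosa identity genes went both ways, 5 higher and 8 lower of 17: KRT13, the keratin of non-cornified mucosa, was 5.5-fold lower in HaCaT, at 160.4 ± 4.57 against 882 ± 76.1 CPM, and KRT4 was higher. Wound-activated keratins and alarmins were higher for 6 of 13 and lower for 5, with a median log2 of 0.08 and a mean of -0.32. Simple-epithelial keratins were higher for 3 of 7 and lower for 4; their median was -0.66 and their mean 1.59, and camera pointed up. KRT19 stood at 1354 ± 42.5 against 4666 ± 498 CPM. Of 24 matrix proteases and inhibitors 12 were higher and 8 lower, with MMP2 11.2-fold higher and TIMP3 7.56-fold lower. Genes of immortalised cells were higher for 1 of 7 and lower for 4; the 1 higher was BMI1, 5.31-fold. Markers of immune cells were lower for 3 of 4, of endothelium lower for 3 and higher for 1 of 4, and of melanocytes lower for 2 and higher for 1 of 4. Mitochondrially encoded transcripts were higher for 8 of 13 and lower for 1. Median, mean or test also differed in sign at 0 h for immediate-early genes, growth factors and NRF2 targets. In all, 10894 genes differed at 0 h, 5101 higher and 5793 lower, of 17409 tested, and 5365 of them differed by at least 1 log2 unit.

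At 6 h after the scratch, FN1 stood at 261 ± 11.8 CPM in HaCaT and 1432 ± 44.6 in TIGK, 5.49-fold lower. Mesenchymal transition genes were lower for 12 of 17 and higher for 1 (adjusted p = 7.7e-05, adjusted p = 0.027 with an estimated correlation). Interferon-stimulated genes were lower for 35 of 40 and higher for 1 (lower for 36 adjusted over the list alone; adjusted p = 2.8e-09, adjusted p = 0.34 with an estimated correlation). BST2 stood at 0.387 ± 0.334 against 289.9 ± 11.9 CPM. All 6 fibroblast markers were lower (adjusted p = 0.0036, adjusted p = 0.1 with an estimated correlation). Differentiation genes were higher for 24 of 38 and lower for 4 (adjusted p = 4.6e-05, adjusted p = 0.34 with an estimated correlation), with KRT1 at 1150 ± 242 against 28.3 ± 8.92 CPM. HOX genes were higher for 20 of 30 and lower for 4 (adjusted p = 0.0012, adjusted p = 0.1 with an estimated correlation). G2/M genes were higher for 31 of 33 (adjusted p = 1.1e-10, adjusted p = 0.34 with an estimated correlation). S phase genes were lower for 20 and higher for 6 of 31 (adjusted p = 0.0098, adjusted p = 0.44 with an estimated correlation). Hypoxia genes were lower for 20 and higher for 2 of 26 (adjusted p = 0.0018, adjusted p = 0.34 with an estimated correlation). Beyond the genes named at 0 h, the largest differences toward HaCaT were HS3ST2 (98.6 ± 4.17 against 0.37 ± 0.146 CPM, 264-fold), PCSK5, PLIN2, HOXC12 and STAC, the last 4 from 75.1-fold to 177-fold. Toward TIGK they were G0S2, a regulator of fat breakdown (0 against 69.95 ± 8.63 CPM, at least 377-fold lower), ZNF469, the carboxypeptidase M gene CPM and CHST10, at least 166-fold to 217-fold lower, and the matrix protein FBLN2, with 1 count in HaCaT and 168 ± 12.7 CPM in TIGK. TERT and CDKN2A were 5.99-fold and 7.19-fold lower. Of the 10900 genes called at 6 h, 5188 were higher and 5712 lower. Median, mean and test differed in sign for 6 lists that were not called: wound keratins, simple-epithelial keratins, integrins, immediate-early genes, growth factors and YAP targets.

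At 24 h the interferon-stimulated genes parted further: all 40 were lower in HaCaT (adjusted p = 5.4e-21, adjusted p = 0.037 with an estimated correlation). IFI6 stood at 4.63 ± 1.68 against 1460 ± 273 CPM, 314-fold lower. IFI44L had 2 counts in HaCaT and 203 ± 18.9 CPM in TIGK. Inflammatory cytokines and chemokines were higher in HaCaT for 15 of 25 and lower for 6 (adjusted p = 0.013, adjusted p = 0.037 with an estimated correlation), led by TNFAIP3, an inhibitor of NF-kB signalling, at 274 ± 19 against 35.9 ± 4.38 CPM, and the neutrophil chemokine CXCL8, at 61.9 ± 7.65 against 6.67 ± 0.55. Immediate-early genes were higher for 23 of 32 and lower for 3 (adjusted p = 6.8e-05, adjusted p = 0.36 with an estimated correlation), with EGR1 10.9-fold and FOSL1 6.04-fold higher. Cholesterol synthesis genes were higher for 13 of 24 and lower for 4 (adjusted p = 0.0046, adjusted p = 0.037 with an estimated correlation), with INSIG1 at 596 ± 21.3 against 148 ± 6.83 CPM. Differentiation genes were higher for 22 of 38 and lower for 3 (adjusted p = 0.00019, adjusted p = 0.39 with an estimated correlation): KRT1 stood at 2535 ± 469 against 127 ± 32.6 CPM and the desmosomal cadherin DSG1 at 147 ± 25.2 against 12.1 ± 1.49. HOX genes were higher for 19 of 30 and lower for 4 (adjusted p = 0.00079, adjusted p = 0.037 with an estimated correlation). Mesenchymal genes were lower for 12 of 17 and higher for 2 (higher for 3 adjusted over the list alone; adjusted p = 0.0018, adjusted p = 0.037 with an estimated correlation), and all 6 fibroblast markers were lower (adjusted p = 0.00095, adjusted p = 0.037 with an estimated correlation). DCN stood at 0.612 against 230 ± 23.6 CPM. G2/M genes were higher for 21 of 33 and lower for 2 (adjusted p = 0.00085, adjusted p = 0.48 with an estimated correlation). New among the largest differences toward HaCaT were WSCD2 and DSG4, at least 162-fold and 123-fold higher, LUZP2, SYN1 and MTUS2. Toward TIGK, NYNRIN, HENMT1, ARSD and NETO1 had no count in HaCaT and were at least 139-fold to 247-fold lower. TERT was 5.54-fold and CDKN2A 7.83-fold lower. Of the 10734 genes called, 4974 were higher and 5760 lower. The lines kept most differences: 3496 genes were higher in HaCaT at all 3 times, with 434 by chance, and 4226 were lower, with 629 by chance, while 217 genes were called in opposite directions at 0 h and 24 h.

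**Figure D1:**
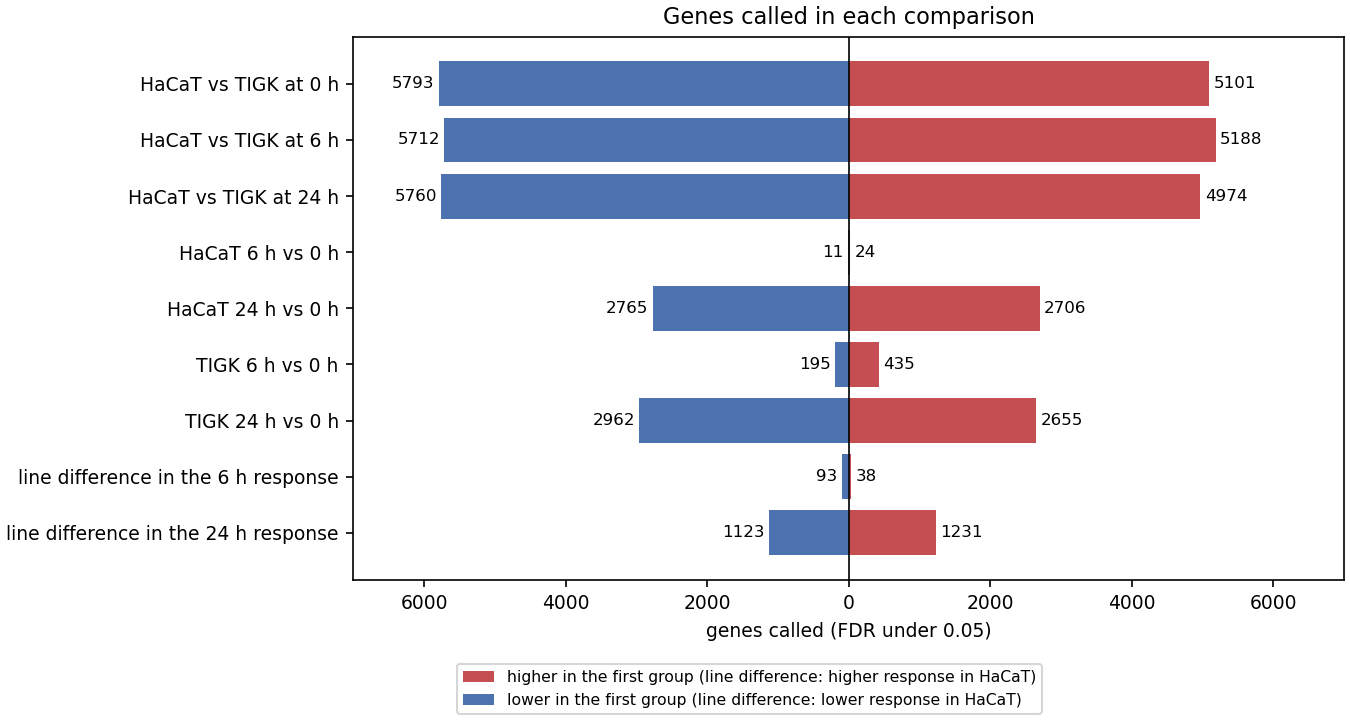
Number of genes called in each of the 9 comparisons (edgeR, false discovery rate under 0.05), with genes higher in the first group drawn to the right and lower ones to the left on one linear axis. The bars run from 35 genes in all for HaCaT at 6 h to 10900 between the lines at 6 h.

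In HaCaT few genes were called at 6 h after the scratch, and the number depended on which libraries were fitted. The early stress transcription factors ATF3 and NR4A1 rose 2.25-fold and 2.23-fold, from 4.48 ± 0.512 to 10.1 ± 0.351 CPM and from 6.18 ± 2.42 to 13.8 ± 0.875 (adjusted p = 0.0016 and 0.0071). IL1RL1, the receptor of interleukin-33, rose from 17.9 ± 4.35 to 38.6 ± 1.57 CPM, and the signal proteins BMP6 and INHBA rose 1.89-fold and 1.62-fold. TNFAIP3 rose 1.64-fold, the protease inhibitor TFPI2 1.87-fold and RGS20 1.68-fold. CXCL8 rose from 2.09 ± 0.953 to 5.15 ± 1.48 CPM. FOXN1, a transcription factor of keratinocyte differentiation, fell 1.68-fold from 20.4 ± 2.73 to 12.1 ± 1.18 CPM, TGM1, which cross-links the cornified envelope, fell 1.46-fold, and TP73, SMAD6, USH1G, PLEKHA6, TSC22D3 and FGFR3 fell 1.37-fold to 1.65-fold. TERT and CDKN2A did not pass (adjusted p = 0.97 and 0.99). Of 32 immediate-early genes 4 rose (14 rose and 2 fell adjusted over the list alone), among them FOSL1, from 185 ± 17.4 to 291 ± 25.9 CPM, and KLF6, 1.35-fold (list adjusted p = 1.6e-09, adjusted p = 0.12 with an estimated correlation). Of the integrin and wound matrix list 0 of 24 passed over all genes (5 rose and 1 fell adjusted over the list alone; list adjusted p = 8.5e-05, adjusted p = 0.37 with an estimated correlation); its thrombospondin THBS1 stood at 1432 ± 131 and 1957 ± 98.5 CPM at 0 h and 6 h. Of 24 proteases and inhibitors 2 rose (5 adjusted over the list alone; list adjusted p = 0.015, adjusted p = 0.18 with an estimated correlation), and of 25 inflammatory genes 2 rose (4 adjusted over the list alone; list adjusted p = 0.02, adjusted p = 0.12 with an estimated correlation). The differentiation list was called upward although its 1 member that passed, TGM1, fell (6 rose and 1 fell adjusted over the list alone; list adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation).

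A further 6 lists were called in HaCaT at 6 h with 0 members passing over all genes. Wound-activated keratins (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.025, adjusted p = 0.53 with an estimated correlation) and antimicrobial genes (adjusted p = 0.029, adjusted p = 0.12 with an estimated correlation) were called upward. Oral mucosa identity genes (1 fell adjusted over the list alone; adjusted p = 0.029, adjusted p = 0.37 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.024, adjusted p = 0.12 with an estimated correlation) were called downward. So were fibroblast markers (1 fell adjusted over the list alone; adjusted p = 0.035, adjusted p = 0.18 with an estimated correlation) and immune cell markers (adjusted p = 0.015, adjusted p = 0.12 with an estimated correlation). The fibroblast call is lost in the replicate block by letter within line, at 0.058. In all, edgeR called 35 genes, 24 up and 11 down, while 1315 had an unadjusted p under 0.05. The count depends on single libraries and settings: it was 4 without HaCaT 0 h B, 107 with DESeq2, 70 with the replicate block within line, and 200 when only the HaCaT 0 h and 6 h libraries were fitted. Without the TIGK letter C libraries, which enter this comparison only through the shared filter, scaling and spread, it was 172. Of the 16 genes with the largest changes, 13 lose their call without HaCaT 0 h B, 12 without 0 h A, 4 without 0 h C, 10 without any 1 of the 6 h libraries, and 7 with limma-trend on FPKM.

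By 24 h HaCaT cells had raised inflammatory, immediate-early, hypoxia and cholesterol synthesis genes. CXCL8 (chr 4, 73740506 to 73743716) rose from 2.09 ± 0.953 to 61.9 ± 7.65 CPM, 29.5-fold (log2 4.88, SE 0.24, adjusted p = 1.8e-13), CXCL1 rose 26.5-fold, and the cytokine IL1A rose from 3.36 ± 0.817 to 34.5 ± 1.37 CPM. BIRC3, an inhibitor of cell death, rose 10.2-fold to 96 ± 2.61 CPM, EGR1 (chr 5, 138465490 to 138469315) 9.36-fold to 387 ± 31.7 CPM and FOS 9.08-fold to 96 ± 5.54 CPM; SH2D3C and SOX6 rose 12.4-fold and 9.89-fold. The matrix protease MMP3 (chr 11, 102835801 to 102843803) fell from 18 ± 5.47 to 0.35 ± 0.0285 CPM, 50.4-fold (adjusted p = 1.3e-11). IL1RL1 and BMP6, which had risen at 6 h, stood below 0 h at 24 h, 23.1-fold and 12.2-fold lower; AKAP12, KCNMA1, NTSR1, GPAT3 and SH2D5 fell 4.22-fold to 6.86-fold. TERT fell 2.7-fold to 2.11 ± 0.341 CPM, and CDKN2A rose 1.21-fold to 55.5 ± 4.13. Of 25 inflammatory genes 17 rose and 1 fell (adjusted p = 2.4e-12, adjusted p = 9e-05 with an estimated correlation), with TNFAIP3 7.26-fold and NFKBIA 3.35-fold higher. Of 32 immediate-early genes 24 rose and 2 fell (adjusted p = 2.4e-12, adjusted p = 0.048 with an estimated correlation). Of 26 hypoxia and glycolysis genes 21 rose (22 adjusted over the list alone; adjusted p = 1.1e-12, adjusted p = 0.021 with an estimated correlation). Adrenomedullin (ADM) rose from 80.9 ± 1.55 to 313 ± 21.9 CPM and NDRG1 from 539 ± 3 to 1722 ± 186. Of 24 cholesterol synthesis genes 20 rose (adjusted p = 1.1e-11, adjusted p = 0.00018 with an estimated correlation). HMGCS1 rose from 134 ± 3.15 to 284 ± 11.6 CPM.

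Stress lists rose with them in HaCaT at 24 h. The unfolded protein and integrated stress response list had 16 of 26 risen and 1 fallen (20 and 1 adjusted over the list alone; adjusted p = 1.5e-06, adjusted p = 0.023 with an estimated correlation). DDIT4 rose from 434 ± 22.4 to 1287 ± 103 CPM. NRF2 and aryl hydrocarbon receptor targets had 11 of 21 risen (11 and 1 fallen adjusted over the list alone; adjusted p = 0.00021, adjusted p = 0.011 with an estimated correlation). GCLC, an enzyme of glutathione synthesis, was 1.85-fold higher. Targets of p53 had 12 of 25 risen and 5 fallen (14 and 5 adjusted over the list alone; adjusted p = 0.0094, adjusted p = 0.032 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 59.6 ± 3.14 to 214 ± 9.43 CPM. G2/M genes had 24 of 33 risen (24 and 1 fallen adjusted over the list alone; adjusted p = 3.2e-08, adjusted p = 0.39 with an estimated correlation). TOP2A was 1.9-fold higher. Differentiation genes had 17 of 38 risen and 2 fallen (18 and 2 adjusted over the list alone; adjusted p = 0.00034, adjusted p = 0.4 with an estimated correlation). TGM1 rose from 74.6 ± 6.42 to 160 ± 4.71 CPM and DSG1 rose 3.89-fold. TGF-beta targets had 11 of 20 risen and 5 fallen (11 and 6 adjusted over the list alone; adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation), and went both ways: BHLHE40 rose 4.46-fold and PMEPA1 fell 2.69-fold. Integrins and wound matrix genes had 4 of 24 risen and 12 fallen (4 and 13 adjusted over the list alone; adjusted p = 0.0031, adjusted p = 0.57 with an estimated correlation). The integrin chain ITGB1 fell from 835 ± 15.7 to 487 ± 15.4 CPM. The interferon list was not called in HaCaT (8 rose and 1 fell, adjusted p = 0.053), and passed in the replicate block within line (0.032) and without the 2 TIGK libraries that list more genes (0.041). Markers of fibroblasts, melanocytes, immune cells and endothelium were not called (adjusted p 0.18 to 0.75), nor were mitochondrially encoded transcripts (0.25). Proteases had a median log2 of 0.06 and a mean of -0.09 and were not called, with MMP13 7.21-fold higher beside the fall in MMP3; HOX genes differed in sign too and were not called. Of the 5471 genes called, 2706 rose and 2765 fell.

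**Figure D2:**
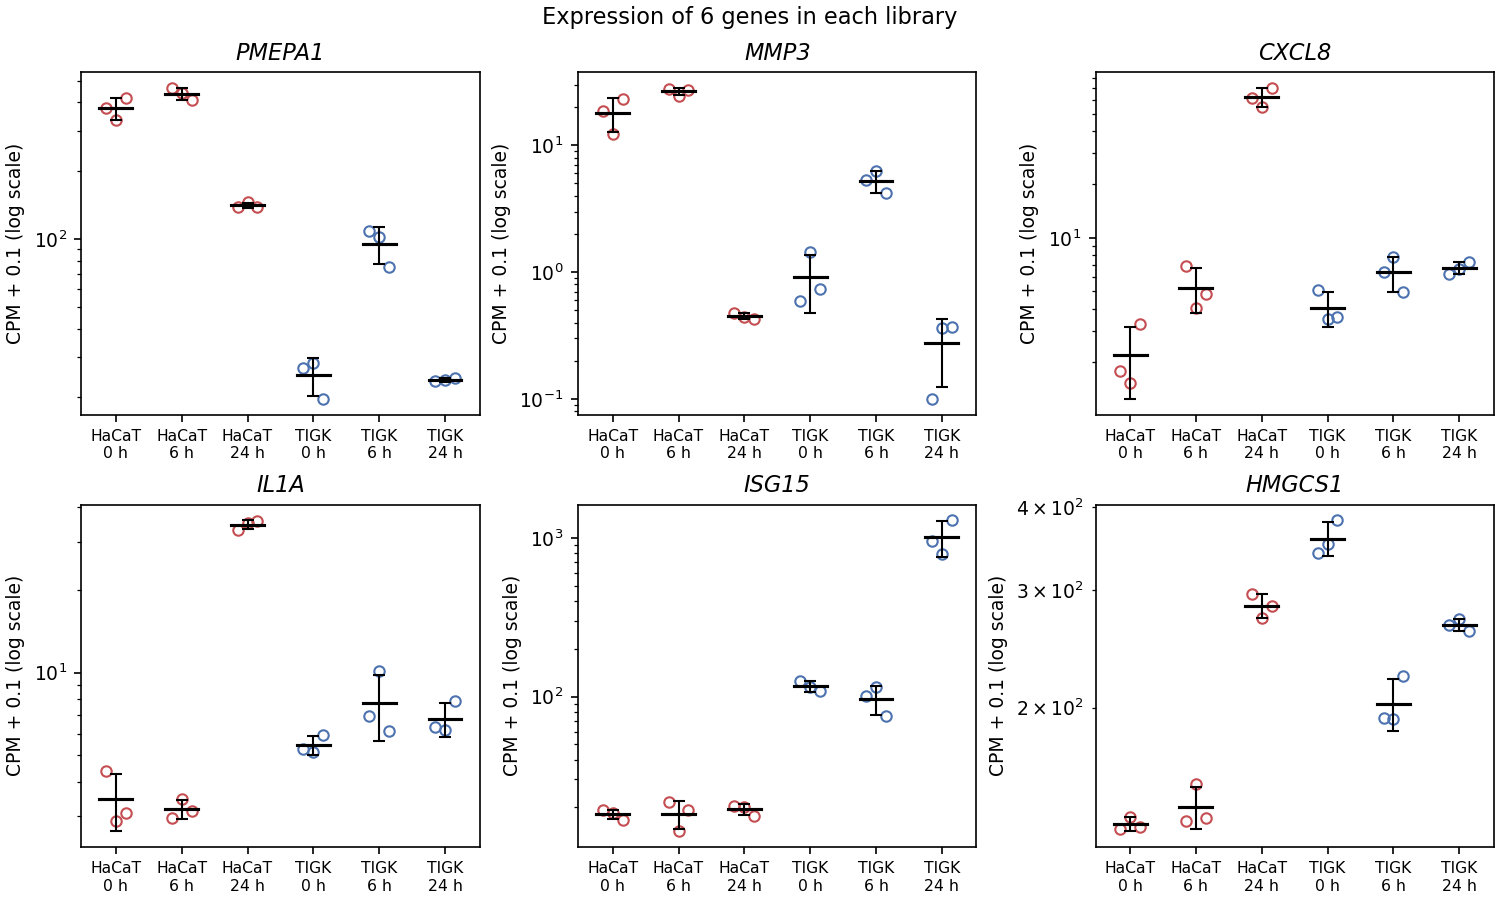
CPM + 0.1 on a log scale of 6 genes in each of the 18 libraries (open points), with the mean (line) and SD (bar) of the 3 libraries of each group; HaCaT is red and TIGK blue. In TIGK, PMEPA1 is highest at 6 h (94.9 CPM). Over all groups, CXCL8 is highest in HaCaT at 24 h (61.9 CPM) and ISG15 in TIGK at 24 h (1015 CPM).

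In TIGK more genes were called at 6 h than in HaCaT. Of the 11 lists called, cholesterol synthesis and mesenchymal genes keep the call with an estimated correlation. PMEPA1, a TGF-beta target (chr 20, 57648392 to 57711536), rose from 24.9 ± 4.68 to 94.9 ± 17.3 CPM, 3.84-fold (log2 1.94, SE 0.13, adjusted p = 5.3e-10). The collagenase MMP1 rose from 8.07 ± 1.69 to 28.8 ± 0.851, and IL1RL1 from 5.17 ± 1.48 to 20.2 ± 1.29. NFATC2, the cholesterol exporter ABCA1, G0S2 and the receptor S1PR1 rose 2.68-fold to 3.48-fold. The secreted proteins SMOC1 and VGF fell 6.34-fold and 3.51-fold, from 18 ± 2.6 to 2.83 ± 0.235 CPM and from 124 ± 32.8 to 35.4 ± 4.82, and MAP2K6, MCF2L, FOXO4 and OSBP2 fell 2.22-fold to 2.3-fold. CBSL (14.1-fold lower) and GPR89B (2.79-fold lower) have near-identical copies whose reads they may hold, and CBSL varied from library to library at 0 h (10.8 ± 8.48 CPM). Without TIGK 0 h C and 6 h C the calls of CBSL, MCF2L and GPR89B are lost (0.055, 0.05 and 0.2), and that of GPR89B also without TIGK 0 h C, 6 h A or 6 h B (0.075 to 0.14). TERT and CDKN2A did not pass (adjusted p = 0.46 and 0.88). Of 24 integrin and wound matrix genes 10 rose (14 rose and 2 fell adjusted over the list alone; adjusted p = 4.4e-13, adjusted p = 0.078 with an estimated correlation). THBS1 rose from 737 ± 73.9 to 1919 ± 102 CPM, FN1 rose 2.16-fold and the integrin chains ITGB6 and ITGA2 rose 2.33-fold and 2.19-fold. Of 16 basal keratinocyte genes 5 rose and 1 fell (10 and 1 adjusted over the list alone): the laminin chains LAMB3 and LAMA3 rose 2.1-fold and 2.16-fold and the transcription factor TP63 1.55-fold (adjusted p = 8.4e-09, adjusted p = 0.058 with an estimated correlation). Of 24 cholesterol synthesis genes 12 fell (16 adjusted over the list alone; adjusted p = 5.5e-16, adjusted p = 5.6e-05 with an estimated correlation). HMGCS1 fell from 359 ± 21.2 to 203 ± 17.9 CPM.

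Other lists also moved in TIGK at 6 h. Immediate-early genes rose for 13 of 32 (15 adjusted over the list alone; adjusted p = 8.9e-14, adjusted p = 0.058 with an estimated correlation). FOSL1 was 1.84-fold and JUN 1.72-fold higher. Mesenchymal transition genes rose for 2 of 17 (3 adjusted over the list alone), FN1 and SNAI2 (adjusted p = 0.0003, adjusted p = 0.033 with an estimated correlation). TGF-beta targets rose for 6 of 20 and fell for 1 (10 and 3 adjusted over the list alone; adjusted p = 1.1e-07, adjusted p = 0.13 with an estimated correlation). YAP targets rose for 5 of 22 (7 adjusted over the list alone; adjusted p = 5.4e-06, adjusted p = 0.16 with an estimated correlation). Tissue factor (F3) was 1.54-fold higher. Proteases and inhibitors rose for 5 of 24 and fell for 2 (7 and 2 adjusted over the list alone; adjusted p = 0.00062, adjusted p = 0.081 with an estimated correlation). MMP3 rose from 0.821 ± 0.445 to 5.16 ± 1.05 CPM. Growth factors rose for 6 of 30 and fell for 1 (10 and 4 adjusted over the list alone; adjusted p = 0.002, adjusted p = 0.23 with an estimated correlation). INHBA was 2.19-fold and NRG1 1.55-fold higher. Interferon-stimulated genes fell for 9 of 40 (1 rose and 16 fell adjusted over the list alone; adjusted p = 3.7e-07, adjusted p = 0.25 with an estimated correlation). From the 0 h mean, the list median stood at 0.24, -0.06 and -0.17 log2 in the 0 h A, B and C libraries and at -0.18, -0.20 and -0.66 in those of 6 h. Without the 2 letter C libraries of 0 h and 6 h the list is still called (0.00019). DDX60 fell from 61.7 ± 10.3 to 36.6 ± 8.44 CPM. G2/M genes fell for 3 of 33 (13 adjusted over the list alone; adjusted p = 1.6e-09, adjusted p = 0.23 with an estimated correlation). Mitochondrially encoded transcripts had 0 of 13 passing and were not called (adjusted p = 0.082). They were called without the 2 libraries that list more genes (0.0017) and in the replicate block by letter within line. Wound keratins (median log2 0.03, mean -0.27) and oral mucosa genes differed in sign and were not called. Of the 630 genes called, 435 rose and 195 fell. When only the TIGK 0 h and 6 h libraries were fitted 359 were called, against 200 in HaCaT fitted in the same way. Without TIGK 6 h B 350 were called and without TIGK 6 h A 381.

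By 24 h all 40 interferon-stimulated genes had risen in TIGK (adjusted p = 9.3e-33, adjusted p = 0.047 with an estimated correlation). ISG15 (chr 1, 1001138 to 1014540) rose from 116 ± 8.72 to 1015 ± 255 CPM, 8.75-fold (log2 3.13, SE 0.16, adjusted p = 5e-13), RSAD2 from 4.06 ± 1.77 to 39.7 ± 10.3, IFITM1 from 17.1 ± 3.23 to 138 ± 27.3, IFI44L from 30.4 ± 8.93 to 203 ± 18.9, and CMPK2 8.45-fold. Outside that list ATOH8 rose from 0.734 ± 0.0858 to 12.1 ± 1.33 CPM, the pattern recognition receptor CLEC7A 13.8-fold and the ubiquitin ligase FBXO32 6.86-fold. NPTX1 (chr 17, 80467148 to 80477843) fell from 243 ± 24.8 to 9.47 ± 2.49 CPM, 25.5-fold (adjusted p = 4.7e-17), and BMP6, SYT12, VGF, FAM43B, DAW1, APLN and KIAA1549L fell 6.29-fold to 12.8-fold. TERT fell 3.26-fold to 11.7 ± 2.3 CPM and CDKN2A rose 1.33-fold to 435 ± 62.4. Of 33 G2/M genes 32 rose (33 adjusted over the list alone; adjusted p = 3.8e-20, adjusted p = 0.12 with an estimated correlation). TPX2 and CCNB2 were 2.14-fold and 2.63-fold higher. Of 31 S phase genes 19 fell and 1 rose (adjusted p = 3.9e-06, adjusted p = 0.19 with an estimated correlation). CDC6 was 1.64-fold lower. Of 26 hypoxia and glycolysis genes 13 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0043, adjusted p = 0.31 with an estimated correlation). VEGFA fell from 139 ± 10.8 to 85.2 ± 3.8 CPM. TGF-beta targets rose for 10 of 20 and fell for 3 (10 and 4 adjusted over the list alone; adjusted p = 0.0012, adjusted p = 0.31 with an estimated correlation). ID3 rose from 102 ± 10.5 to 382 ± 49.5 CPM and SMAD6 rose 4.5-fold.

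Basal keratinocyte genes rose in TIGK at 24 h for 10 of 16 and fell for 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00052, adjusted p = 0.19 with an estimated correlation). CXCL14 rose from 64.4 ± 12.1 to 361 ± 57.6 CPM and KRT14 from 7355 ± 348 to 10796 ± 1466. Differentiation genes rose for 12 of 38 and fell for 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0043, adjusted p = 0.45 with an estimated correlation). KRT1 was 3.6-fold and the transcription factor GRHL3 3-fold higher. Targets of p53 rose for 11 of 25 and fell for 3 (13 and 3 adjusted over the list alone; adjusted p = 0.0097, adjusted p = 0.097 with an estimated correlation). CDKN1A was 2.25-fold and BBC3 3.95-fold higher. The unfolded protein and stress response list rose for 11 of 26 and fell for 1 (adjusted p = 0.0069, adjusted p = 0.19 with an estimated correlation). The chaperone HSPA5 was 1.44-fold higher. Of 6 fibroblast markers 5 rose (adjusted p = 0.0069, adjusted p = 0.12 with an estimated correlation), with DCN from 100.4 ± 19.8 to 230 ± 23.6 CPM. Of 13 mitochondrially encoded transcripts 8 rose (adjusted p = 0.045, adjusted p = 0.48 with an estimated correlation). MT-CO3 rose from 7022 ± 1367 to 9717 ± 649 CPM. Markers of melanocytes, immune cells and endothelium were not called (adjusted p 0.38 to 0.59). Immediate-early genes (13 rose and 6 fell, 14 and 7 adjusted over the list alone; adjusted p = 0.079) and inflammatory genes (7 rose, 1 fell, adjusted p = 0.18; median log2 0.20, mean -0.01) were not called; EGR1 stood at 28.98 ± 5.45 CPM at 0 h and 35.3 ± 7.73 at 24 h. Proteases, integrins and cholesterol synthesis genes differed in sign between median, mean and test and were not called. Of the 5617 genes called, 2655 rose and 2962 fell.

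The test of the difference between the 6 h responses asked which genes the scratch moved otherwise in one line than in the other. PMEPA1 rose in TIGK from 24.9 ± 4.68 to 94.9 ± 17.3 CPM and stood at 377 ± 42.4 and 437 ± 26.9 in HaCaT, a log2 difference of -1.73 (SE 0.17, adjusted p = 2.6e-06). MMP1 (-1.76), MMP3 (-2.11) and WNT9A (-1.24) also had the larger rise in TIGK, with MMP3 at 18 ± 5.47 and 26.5 ± 1.8 CPM in HaCaT. FOXN1 (-1.21) went from 20.4 to 12.1 CPM in HaCaT and from 12.9 to 17.6 in TIGK. VGF (2.05), CEMIP (1.77) and COBL (1.58) fell more in TIGK. The call of COBL is lost without HaCaT 0 h A (0.051), TIGK 0 h B (0.06) or TIGK 6 h B (0.11), and with limma-trend on FPKM its sign turns (-0.04). MMP3 (0.17), CEMIP (0.069), GPR89B (0.15) and HS6ST2 (0.37) lose their call with limma-trend too. MCF2L (1.86) passed narrowly, at 0.047. Its call is lost in the common replicate block, without TIGK letter C (0.064), without TIGK 0 h C and 6 h C (0.089), and without any 1 library but HaCaT 6 h C (0.054 to 0.16). GPR89B (2.44) has a near-identical copy, and loses its call without TIGK 0 h C and 6 h C (0.059) and without HaCaT 0 h A, 0 h B or 6 h C or TIGK 0 h C, 6 h A or 6 h B (0.053 to 0.12). HS6ST2 (5.64) rests on 0 counts in HaCaT at 0 h and 16 counts at 6 h, so its value is no measure of size. TERT and CDKN2A did not pass (adjusted p = 0.86 and 0.99). Basal keratinocyte genes had the lower response in HaCaT for 4 of 16 (1 higher and 10 lower adjusted over the list alone; adjusted p = 2.5e-08, adjusted p = 0.061 with an estimated correlation). The log2 difference of LAMB3 was about -1 and that of TP63 -0.66. Integrins and wound matrix genes had it for 5 of 24 (2 higher and 6 lower adjusted over the list alone; adjusted p = 1.7e-05, adjusted p = 0.37 with an estimated correlation), with THBS1 at -0.93. TGF-beta targets had it for 6 of 20 (8 adjusted over the list alone; adjusted p = 8.1e-08, adjusted p = 0.19 with an estimated correlation). Mesenchymal genes had it for 1 of 17, FN1 at -0.96 (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.0011, adjusted p = 0.052 with an estimated correlation). Cholesterol synthesis genes had the higher response in HaCaT for 6 of 24 (9 adjusted over the list alone; adjusted p = 2.4e-08, adjusted p = 0.0014 with an estimated correlation). HMGCS1 had a log2 difference of 0.91.

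At 6 h the interferon list had the higher response in HaCaT for 1 of 40, DDX60 at 0.87 (5 adjusted over the list alone; adjusted p = 3.9e-05, adjusted p = 0.43 with an estimated correlation). The G2/M list was called toward HaCaT with 0 members passing (adjusted p = 1.4e-07, adjusted p = 0.4 with an estimated correlation). YAP targets (adjusted p = 0.02, adjusted p = 0.49 with an estimated correlation) and oral mucosa genes (3 lower adjusted over the list alone; adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation) were called toward TIGK with 0 passing. The differentiation list was called toward HaCaT although its 1 member that passed, TGM1, had the lower response there (adjusted p = 0.03, adjusted p = 0.58 with an estimated correlation), and that call is lost without the 2 TIGK libraries that list more genes (0.21). Inflammatory genes had a median log2 of -0.01 (0.00 with members lacking counts in a group set to their bound) and a mean of 0.45 and were not called. In all, 131 genes differed, 38 with the higher and 93 with the lower response in HaCaT. The replicate block within line gave 212, DESeq2 300, leaving out TIGK letter C 357, and leaving out TIGK 6 h B 68.

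At 24 h the lines went separate ways in interferon, inflammatory and hypoxia genes. ISG15 rose to 1015 ± 255 CPM in TIGK and stood at 18 ± 1.23 and 19.4 ± 1.53 in HaCaT at 0 h and 24 h, a log2 difference of -3.02 (SE 0.23, adjusted p = 2.1e-09). IFITM1 (-3.10), IFI6 (-2.62) and DDX60L (-2.93) did likewise, and the interferon list had the lower response in HaCaT for 31 of 40 (32 adjusted over the list alone; adjusted p = 4e-30, adjusted p = 0.016 with an estimated correlation). CXCL8 (4.12), IL1A (3.04), TNFAIP3 (2.42) and ICAM1 (2.01) had the higher response in HaCaT, and the inflammatory list had it for 13 of 25 and the lower for 1 (15 and 1 adjusted over the list alone; adjusted p = 1.7e-11, adjusted p = 0.00014 with an estimated correlation). Hypoxia and glycolysis genes had it for 20 of 26 (23 adjusted over the list alone; adjusted p = 1.8e-21, adjusted p = 0.0041 with an estimated correlation). Hexokinase 2 (HK2) had a log2 difference of 1.76, ENO2 of 3.60 and VEGFA of 1.32. Cholesterol synthesis genes had it for 16 of 24 (18 adjusted over the list alone; adjusted p = 3.6e-12, adjusted p = 0.00014 with an estimated correlation), with HMGCS1 at 1.52. Immediate-early genes had it for 17 of 32 and the lower for 1 (22 and 1 adjusted over the list alone; adjusted p = 4.7e-12, adjusted p = 0.074 with an estimated correlation). EGR1 had a log2 difference of 2.94. MMP3 (-3.51) fell in HaCaT from 18 ± 5.47 to 0.35 ± 0.0285 CPM and stood at 0.821 ± 0.445 and 0.178 ± 0.154 in TIGK. This line difference loses its call without TIGK 24 h B or C (0.12 each) or TIGK letter C (0.13). TLL1 had 13 and 1 counts in HaCaT and 15 ± 2.89 and 15.9 ± 2.47 CPM in TIGK, and loses its call without any 1 of 6 libraries (HaCaT 0 h B and 24 h B and C, TIGK 0 h B and C and 24 h B, at 0.051 to 0.2). The 6 largest differences the other way rest on a group without counts: HaCaT at 0 h for ZNF469, SMOC1, KCNJ12 and ESPNL, with 4 to 6 counts at 24 h, and TIGK at 24 h for HS3ST2 and PLIN2. The call of KCNJ12 is lost without any 1 of HaCaT 0 h A, B and C and 24 h A and B (0.057 to 0.1), that of ESPNL without any 1 of HaCaT 0 h A, B and C and 24 h A and C (0.071 to 0.099), and that of SMOC1 without HaCaT 24 h A (adjusted p = 1). With limma-trend on FPKM, ESPNL (0.084) and TLL1 (0.66) lose their call and HS3ST2 turns its sign without a call (-0.27). TERT and CDKN2A did not pass (adjusted p = 0.55 and 0.53).

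Basal keratinocyte genes had the lower 24 h response in HaCaT for 10 of 16 and the higher for 1 (12 and 2 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.097 with an estimated correlation). LAMA3 fell from 1040 ± 73.3 to 635 ± 12.9 CPM in HaCaT and rose from 299 ± 18.5 to 490 ± 38.8 in TIGK. Integrins and wound matrix genes had it for 11 of 24 and the higher for 2 (13 and 3 adjusted over the list alone; adjusted p = 0.0003, adjusted p = 0.36 with an estimated correlation). FN1 and ITGB6 had log2 differences of -1.18 and -1.36. Wound-activated keratins and alarmins had the lower response for 5 of 13 (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.023, adjusted p = 0.5 with an estimated correlation). S100A10 had a log2 difference of -0.86. G2/M genes had it for 9 of 33 (12 adjusted over the list alone; adjusted p = 1.3e-06, adjusted p = 0.36 with an estimated correlation). S phase genes had the higher response for 12 of 31 (16 adjusted over the list alone; adjusted p = 2.7e-08, adjusted p = 0.097 with an estimated correlation). NRF2 targets had the higher response for 6 of 21 and the lower for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.026, adjusted p = 0.097 with an estimated correlation). The stress response list had it for 8 of 26 and the lower for 2 (11 and 3 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.35 with an estimated correlation). DDIT4 had a log2 difference of 1.27. Mitochondrially encoded transcripts had the lower response for 4 of 13 (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.0023, adjusted p = 0.35 with an estimated correlation). Differentiation, oral mucosa, mesenchymal, p53 target and YAP target genes and immune and endothelial markers differed in sign between median, mean and test and were not called. In all, 2354 genes differed, 1231 with the higher and 1123 with the lower response in HaCaT.

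**Figure D3:**
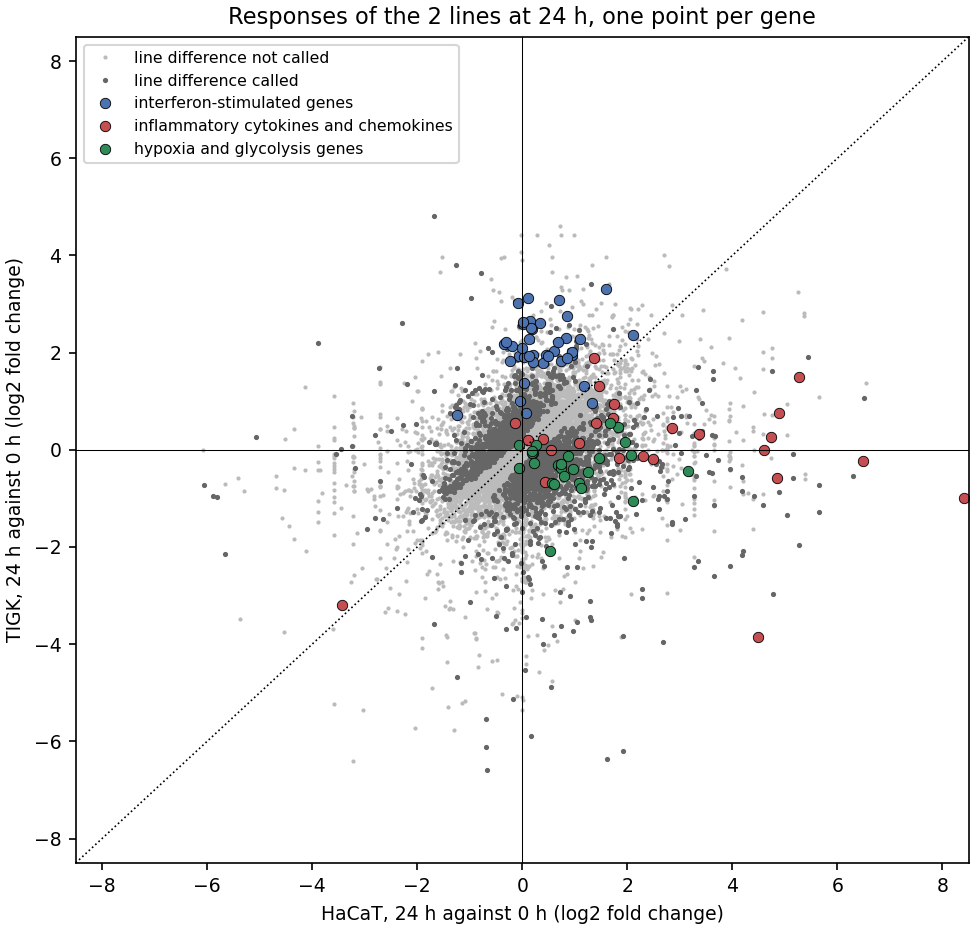
Log2 fold change from 0 h to 24 h in HaCaT (x axis) and TIGK (y axis), one point per gene tested, with the dotted line where both are equal; dark grey points are the genes whose line difference was called. Most interferon-stimulated genes (blue) lie above the line, with all 40 raised in TIGK, and most inflammatory (red) and hypoxia genes (green) lie to its right.

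Across all genes, the 6 h responses of the lines had a Pearson r of 0.012 (Spearman rho = 0.045; jackknife SE of r over libraries 0.023; r = 0.085 for genes of at least 5 CPM). Of the 24 genes that rose in HaCaT 15 rose in TIGK too, with 0.6 by chance (31 of 48 with the replicate block within line), and 1 fell in both. The 24 h responses were related (r = 0.294, rho = 0.395; SE 0.028; r = 0.481 for genes of at least 5 CPM): 1189 genes rose in both, with 413 by chance, and 1497 fell in both, with 470 by chance. A further 221 rose in HaCaT and fell in TIGK, with 460 by chance, and 101 did the reverse, with 422 by chance. Genes are not independent replicates, so no p is given for these correlations.

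The authors' deposited table for HaCaT at 24 h lists 4426 genes, 2155 up and 2271 down, and 95.9% of them were called in the same direction here. The authors' deposited table for HaCaT at 6 h lists 154 genes, of which 30 (19.5%) were called here. The authors' deposited table for TIGK at 6 h lists 385 genes (93.5% called here) and the authors' deposited table for TIGK at 24 h lists 3285 (99.3% called here). For the lines at 0 h, one of the authors' deposited tables lists 1686 genes lower in HaCaT and another 765 higher, and each of these genes that was tested was called here in the same direction. The authors' deposited table for the lines at 6 h lists 2362 genes, 738 higher and 1624 lower (99.8% called here), and a separate one lists 720 higher genes (99.9%). The authors' deposited table for the lines at 24 h lists 2234 genes, 893 higher and 1341 lower (99.8% called here), and a separate one lists 862 higher genes. These whole tables for the lines at 6 h and 24 h hold adjusted p up to 0.071 and 0.12, with 3 and 7 genes at 0.05 or more, while the other tables stay at or under 0.01. None of the genes tested here had the opposite sign to that in the authors' deposited tables. The authors' deposited tables for the lines list only genes with an absolute log2 fold change above 1. Those within a line also list genes with smaller changes. The percentages called here are therefore not comparable between the tables for the lines and those within a line. For the same reason, the numbers listed for the lines are not comparable with the numbers called here.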

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

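The tests of 1 library carrying the interferon rise, of time in culture, of the other splits of the libraries, and of the letter blocks and left-out TIGK C libraries were chosen after the results they test were seen. Results below stand out because the response to the scratch differed between the lines in a direct test of that difference, or because a pattern in the libraries has a technical explanation to weigh.

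The interferon-stimulated genes rose together in TIGK at 24 h, with a list median of 2.06 log2. No single library carries the rise: the lowest TIGK 24 h library had a median of 1.96 over the 0 h mean, and the 3 libraries had 2.10, 1.96 and 2.11, against 0.24, 0.04 and 0.24 in HaCaT. A candidate explanation is interferon made by the TIGK cells themselves, since 3 of 21 type I and III interferon genes had every 24 h library above 3 counts and above every 0 h library: IFNL1 with 12, 14 and 21 counts, IFNL2 with 14, 10 and 5, and IFNL3 with 9, 9 and 15, each against at most 4 at 0 h. IFNL2 and IFNL3 are near-identical and share reads, and the counts are low. IFNB1 had 3, 4 and 5 counts at 24 h against 0 in each 0 h library, with its lowest library not above 3. IFNE went from 17, 28 and 49 counts at 0 h to 9, 20 and 6 at 24 h. Time in culture stays open and cannot be told apart from the scratch, because 0 unscratched libraries were collected at 24 h.

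Neighbouring genes differed between the lines in the same direction over long stretches of chromosomes. Of 162 windows of at least 100 neighbouring genes, 84 had a median line difference at 0 h outside the central 95% of shuffled windows (-0.20 to 0.21 log2), 48 higher and 36 lower in HaCaT, where 100 shuffles gave at most 19, and all 84 had the same sign at 3 times. Examples are chr 4 from 10074339 to 48906937 (median -1.49), chr 18 from 36777647 to 80247546 (1.36), chr 10 from 134465 to 27542237 (1.19) and chr 5 from 92151 to 38845829 (-0.86). GC content and gene length do not account for it, since 95.2% of the windows (80 of 84) stayed outside in the same direction after that trend was removed. Different DNA copy number in the 2 lines is consistent with this and may contribute to the line differences reported for single genes, but no DNA was measured.

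The letter C libraries of TIGK at 0 h and 6 h listed more genes than the other 16. Depth was excluded: thinned to 14238090 counts, they still listed 24456 and 24389 genes, and the others 20950 to 22446. A large carry-over of genomic DNA was not seen: their olfactory receptor reads, 9.56 and 8.59 CPM, lay within the 5.96 to 14.4 of the others (0.597 of the highest, in the lower of the pair). That range is wide and the genes found in the pair alone hold few reads, so a small carry-over is not excluded. RNA of HaCaT cells was excluded, since 20 genes with a median of 53.5 CPM in HaCaT at 24 h stood at 0.2 and 0.111 CPM in the pair, at most 1.03 times the level in the A and B libraries. No biological explanation was tested, and 105 genes had counts in this pair alone, with a median of 3 counts in all. The TIGK 24 h C library listed 21457 genes, yet it also stood apart from its replicates. Its chi-square per degree of freedom was 17.8 against A and 13.4 against B.

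At 6 h, 131 genes differed between the lines in their response, and of 100 splits of the libraries 3 called as many, the real one included; the highest other split called 189. Letters may pair the TIGK libraries of 0 h and 6 h, though their resemblance rests mainly on letter C. Of the 80 splits that part all 3 of these possible pairs, 10 called as many, with 443 the highest other, so chance is not excluded. These 10 all split TIGK by its labelled times, the highest with the TIGK times exchanged, and the splits of the 80 that mixed the TIGK times called at most 1. Whichever way HaCaT was split, the 20 splits by the TIGK times called 83 to 443 genes; which genes they share with the 131 was not counted. At 24 h, 2354 genes differed, and 4 of 100 splits called as many, the real one included; the highest other called 3127. The other 3 kept the HaCaT libraries as labelled and mixed the TIGK times. The 85 that mixed times in both lines called at most 0, since the response to time then adds to the spread within groups. These splits do not test a difference between the lines, so chance is not excluded. For the 7 comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 10894 and 0 between the lines at 0 h, 10900 and 0 at 6 h, 10734 and 0 at 24 h, 35 and 1 for HaCaT at 6 h, 5471 and 0 at 24 h, 630 and 206 for TIGK at 6 h, and 5617 and 0 at 24 h. In each of these only 1 split, the real one, called as many. For TIGK at 6 h, letters may pair the libraries. The splits calling 206 and 162 genes put both letter C libraries on one side. Of the 4 splits that part all 3 letter pairs, the others called 0. The replicate block within line gave 786 genes for TIGK at 6 h and 212 for the line difference at 6 h.

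Among the genes with the largest differences between the 6 h responses, in log2 and HaCaT minus TIGK, were HS6ST2 (5.64, fitted against a group without counts and so no measure of size), GPR89B (2.44), VGF (2.05), MCF2L (1.86), CEMIP (1.77) and COBL (1.58) on the one side, where MCF2L, GPR89B and COBL lose their call without some single libraries, and MMP3 (-2.11), MMP1 (-1.76), PMEPA1 (-1.73), WNT9A (-1.24) and FOXN1 (-1.21) on the other. Of the 10 lists called for the 6 h difference, 9 lose the call with an estimated correlation (cholesterol synthesis keeps it), and the differentiation list also without TIGK 0 h C and 6 h C (0.21). List medians of the 6 h difference were 0.43 for differentiation genes (0.50 with members that a whole group lacks set to their bound), 0.33 for interferon-stimulated genes (0.35), 0.25 for G2/M genes and 0.24 for cholesterol synthesis genes. They were -0.41 for mesenchymal genes (-0.24 with such members at their bound), -0.39 for oral mucosa genes, -0.28 for basal keratinocyte genes, -0.23 for TGF-beta targets, -0.17 for integrins and wound matrix genes and -0.16 for YAP targets.

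For the 24 h responses the genes were ZNF469 (6.28), SMOC1 (6.24), HS3ST2 (5.92), PLIN2 (5.42), KCNJ12 (4.79) and ESPNL (4.76), all fitted against a group without counts and so no measure of size, and MMP3 (-3.51), TLL1 (-3.33, fitted on 13 and 1 counts in HaCaT and no measure of size either), IFITM1 (-3.10), ISG15 (-3.02), DDX60L (-2.93) and IFI6 (-2.62). In TIGK, MMP3 stood at no more than 1.33 CPM at 0 h and 0.27 at 24 h, which left little room to fall. Its value is therefore no firm measure of size, and its call is lost without TIGK 24 h B or C. Of the 13 lists called for the 24 h difference, 9 lose the call with an estimated correlation. List medians of the 24 h difference were 2.01 for inflammatory genes (1.10 with members that a whole group lacks set to their bound), 1.29 for hypoxia genes, 0.73 for immediate-early genes, 0.53 for cholesterol synthesis genes, 0.39 for S phase genes, 0.29 for NRF2 targets and 0.24 for the stress response list. They were -1.77 for interferon-stimulated genes, -0.41 for basal keratinocyte genes, -0.38 for mitochondrially encoded transcripts, -0.34 for wound keratins and alarmins, -0.31 for integrins and wound matrix genes and -0.31 for G2/M genes.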

How the results depend on the processing

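Leaving out TIGK letter C, or the TIGK 0 h C and 6 h C libraries, was chosen after seeing the data, as was the use of column letters for the replicate blocks, which were planned by replicate number and could not be run so because no label ties numbers to columns; the other alternatives were planned. Over all alternatives, 186 values of comparisons stayed about the same and 56 moved, counts by over 1.5 times. Of the list values 1119 kept their direction and side of the threshold, 88 lost a call and 73 gained one. The other 25, not called in the main test, changed direction. Of the named gene values 17022 kept theirs, 403 lost a call and 43 gained one. Another 191, not called in the main test, changed sign, and 2 that were called reversed. The reversed ones, both under limma-trend on log2(FPKM + 1), are the line differences of COBL at 6 h (-0.04) and HS3ST2 at 24 h (-0.27); the cause was not tested. DESeq2 size factors moved the median of all genes by at most 0.021 log2.

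Asking for at least 1 log2 unit as well left 5365, 5374 and 5207 genes between the lines at 0 h, 6 h and 24 h, 8 and 1248 in HaCaT and 72 and 1227 in TIGK at 6 h and 24 h, and 34 and 775 for the line differences, fewer by construction. For HaCaT at 6 h the count was 107 with DESeq2, 130 without a filter, 200 with only the libraries compared, 70 with the replicate block within line, 172 without TIGK letter C, 77 without the TIGK 0 h C and 6 h C libraries, and 20 with limma-trend on FPKM, where 17 rose and 3 fell (85% up, against 68.6%). For TIGK at 6 h it was 359 with only the libraries compared. For the line difference at 6 h it was 300 with DESeq2, 293 without a filter, 212 with the replicate block within line and 357 without TIGK letter C. For HaCaT at 6 h, the TIGK libraries act only through the shared filter, scaling and spread. Which of these changed the count was not tested, nor was the cause of the other changes. The replicate block, common or within line, changed no other count by over 1.5 times. Among lists, the block within line lost the call of basal keratinocyte genes between the lines at 0 h (0.053) and of fibroblast markers in HaCaT at 6 h (0.058), and called the interferon list in HaCaT at 24 h (0.032; 0.048 with the common block) and mitochondrially encoded transcripts in TIGK at 6 h (0.032). Without the TIGK 0 h C and 6 h C libraries, the interferon list was called in HaCaT at 24 h (0.041) and mitochondrially encoded transcripts in TIGK at 6 h (0.0017). For the line difference at 6 h, that alternative called mitochondrially encoded transcripts and immediate-early genes (0.0044 each), and the differentiation list was no longer called (0.21). No other list call changed in these 3 alternatives.

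Without 1 library, the counts ranged from 10288 to 10407 (lines at 0 h), 10247 to 10507 (6 h), 10139 to 10379 (24 h), 4 to 30 and 4575 to 4720 (HaCaT at 6 h and 24 h), 350 to 817 and 4680 to 5236 (TIGK), and 68 to 260 and 1898 to 2273 (line differences at 6 h and 24 h). For HaCaT at 6 h the count was 7 without HaCaT 0 h A, 4 without 0 h B, 8 without 6 h A, 17 without 6 h B and 13 without 6 h C. For TIGK at 6 h it was 381 without TIGK 6 h A and 350 without 6 h B. For the line difference at 6 h it was 71 and 79 without HaCaT 0 h A and C, 72, 85 and 75 without HaCaT 6 h A, B and C, 86 without TIGK 0 h B, and 71, 68 and 260 without TIGK 6 h A, B and C.

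Lists called by camera with an estimated correlation, of 29, were 0 between the lines at 0 h (9 with the preset one), 1 at 6 h (of 8; mesenchymal), 0 for HaCaT at 6 h (of 11), 7 for HaCaT at 24 h (of 11), 2 for TIGK at 6 h (of 11; cholesterol synthesis and mesenchymal), 1 for TIGK at 24 h (of 11; interferon), 1 for the line difference at 6 h (of 10; cholesterol synthesis) and 4 at 24 h (of 13; inflammatory, interferon, cholesterol synthesis and hypoxia). Between the lines at 24 h 6 lists were called. With fry, which does not compare a list with other genes, the counts were 25, 22 and 25 between the lines, 5 and 19 in HaCaT at 6 h and 24 h, 11 and 21 in TIGK, and 4 and 13 for the line differences. Of the lists called by camera, fry lost 6 of 11 in HaCaT at 6 h, 1 of 11 in TIGK at 6 h, and 6 of 10 and 1 of 13 for the line differences at 6 h and 24 h. Across genes, the correlation of the responses was 0.085 at 6 h and 0.481 at 24 h for genes of at least 5 CPM, 0.262 at 24 h without the TIGK 0 h C and 6 h C libraries, and 0.001 to 0.021 and 0.261 to 0.290 without 1 library. In the simulated counts, at 14238090 to 25011331 reads and 3 libraries a group, the smallest fold planted was recovered for 0% to 16% of the genes changed.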

Other observations

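The genes named here lie outside the naming rule and were chosen after their values were seen, for the lowest adjusted p in a comparison. Several had the larger change in one line at 24 h. ERRFI1, a feedback inhibitor of the EGF receptor, rose in HaCaT from 41.4 ± 2.05 to 304 ± 18.7 CPM and in TIGK from 137 ± 7.23 to 219 ± 4.63 CPM (SD, n = 3; line difference 2.19 log2, SE 0.10, adjusted p = 7e-13). TNFAIP2, a TNF-induced gene, rose in HaCaT from 9.59 ± 0.693 to 71.8 ± 3.99 CPM and stood at 35.6 ± 5.95 and 38 ± 1.06 in TIGK (line difference 2.80). ACSS2, which makes acetyl-CoA from acetate, rose in HaCaT from 113 ± 5.49 to 263 ± 12.8 CPM and fell in TIGK from 139 ± 17 to 118 ± 4.76 (line difference 1.46). SP100, a nuclear body protein, rose in TIGK from 40.7 ± 5.46 to 149.5 ± 9.95 CPM and stood at 33.1 ± 0.981 and 29.9 ± 2.53 in HaCaT (line difference -2.02).

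Other genes fell in both lines by 24 h. The chaperone HSPA8 fell in TIGK from 4173 ± 167 to 904 ± 157 CPM (log2 -2.21) and in HaCaT from 2447 ± 137 to 740.5 ± 41.9. Of 2 factors of ribosome assembly, RRP12 fell in HaCaT from 207 ± 4.51 to 58.8 ± 1.8 CPM and in TIGK from 129 ± 6.54 to 55.1 ± 3.99. NOL6 fell in HaCaT from 133 ± 9.26 to 32.3 ± 2.31 CPM and in TIGK from 282 ± 23.6 to 142 ± 12.2. Of 2 enzymes of prostaglandin synthesis, PTGS1 fell in HaCaT from 138 ± 14.2 to 36.7 ± 0.312 CPM and in TIGK from 115 ± 7.51 to 42.2 ± 4.15. PTGES fell in HaCaT from 224 ± 11 to 116.5 ± 2.58 CPM and in TIGK from 258 ± 24.7 to 93.1 ± 7.72. At 6 h the transcription factor ETS1 rose in both lines, 1.51-fold in HaCaT and 1.85-fold in TIGK, and filamin C (FLNC) rose in TIGK from 358 ± 17 to 875 ± 1.21 CPM. PTHLH rose in TIGK from 14.9 ± 2.41 to 37.3 ± 1.2 CPM at 6 h (line difference -0.98).

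Between the lines at 0 h, the lowest adjusted p values also fell on THBS2 (5.38 ± 1.44 CPM in HaCaT and 274 ± 20.6 in TIGK, 50.9-fold lower), the collagen chaperone FKBP10 (0.209 ± 0.217 and 255.5 ± 3.61 CPM, 1178-fold lower) and RBM23 (73.4 ± 1.12 and 1.46 ± 0.137 CPM, 50.8-fold higher). Of protein-coding genes with a mean of at least 20 CPM in one line, 7 had no count in any of the 9 HaCaT libraries (among them NKX2-5, ARSD, IRAK3, IKZF3, PYGO1 and RSPO4) and 2 had none in the 9 TIGK libraries (GALNT5 and OLFM1).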
